A study of Homo sapiens with 12 samples.

How the data were processed

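HepG2 is a human hepatocellular carcinoma cell line that keeps many liver functions. The series holds 12 libraries from wild type HepG2 cells and from HepG2 cells in which ATP7B was knocked out (KO). ATP7B encodes the copper-exporting ATPase that is mutated in Wilson disease. Each line was left untreated or given copper for 24 h, which makes 4 groups of 3 libraries. The labels call them biological replicates and give no copper dose. They name 1 KO line and do not say how or where the gene was edited.

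Per the labels' protocols, 100 ng of total RNA per sample entered a 3′ mRNA sequencing kit (QuantSeq), which makes about 1 fragment per transcript near its polyadenylated end. Fragments of 300 bp were read single-end for 75 bp on a NextSeq500. Per the submitters' processing notes, the tools were STAR 2.3.0 and HTSeq with the hg19 build. The annotation release, the strand setting and the filters are not given in the sources used here. The deposited values are raw counts of reads per gene, 1 column per library, with no normalization by the authors. Each library lists 47634 versioned Ensembl gene IDs, of which 23424 had 0 counts in all 12 libraries. Reads near the 3′ end do not depend on transcript length, so no length correction was applied. Without molecular identifiers, amplified copies of a fragment cannot be told from separate molecules, so intervals and floors below cover counting error only.

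Gene symbols came from the gene name tables and from the GENCODE v29 annotation, used for names alone. They named 33755 of the 47634 IDs, which held 98.9% of all counts. No coordinates are given because the reference at hand is another build than the authors' hg19.

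Totals ran from 976658 to 3829151 counts per library. In the shallowest library, ATP7B KO untreated replicate 2, 3 counts equal 3.07 CPM, and in the deepest, wild type untreated replicate 2, they equal 0.783 CPM. CPM stands for the count divided by the library's total over all genes, scaled to the customary common depth.

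The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 11051 genes, and libraries were scaled by the trimmed mean of M values (TMM). All 12 libraries entered a robust quasi-likelihood fit with 4 group means, so that groups of 3 share an estimate of the spread, whose biological coefficient of variation was 29.1%. The 5 comparisons were copper against untreated in each line, KO against wild type in each treatment, and the difference of the copper effects between the lines (the interaction). P-values were adjusted by the Benjamini-Hochberg method over the 11051 genes and called at 0.05, and this is the adjusted p meant throughout. "Rose" and "fell" refer to genes past that threshold. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic. Group levels are mean CPM ± SD over n = 3.

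Before the data were examined, 34 gene lists with 839 symbols were fixed, and 815 symbols were matched to an ID. Each list of at least 5 tested genes was tested with camera in limma 3.58.1, which compares a list with all other genes, at a preset correlation of 0.01 and with an estimated correlation as an alternative. Camera p-values were adjusted over the lists. Genes named in the text follow a rule fixed at the same time. ATP7B is given in every library. For each comparison the genes with a symbol, an adjusted p under 0.05, replicate CPM values that do not overlap (not asked of the interaction) and a mean of at least 5 CPM were ranked, and the 10 largest changes in each direction were taken, or 5 for the KO against wild type comparison in copper and for the interaction. With 3 libraries against 3, chance alone separates 10% of unchanged genes. In addition, up to 4 members of each described list with the smallest adjusted p may be named. Metallothioneins, HMOX1, SQSTM1, MAP1LC3B, TFEB, HSPA1A, SLC30A1, SLC31A1, ALB and AFP may be named anywhere.

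Where a group had 0 counts of a gene, the fold is a lower bound computed against 3 counts over that group. Where it had 1 to 3 counts, the ratio of pooled CPM is given with an exact 95% counting interval. HSPA1A and HSPA1B had 0 counts in every library. They are near-identical copies, and reads that fit both may have been dropped, so nothing is said of their expression. Other metallothionein, histone and paralog counts may share reads and are uncertain for single members.

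The steps were tested on simulated counts with 200 changed genes at real means, depths and spreads. The 30 tested proteasome genes were also raised 2-fold, and the shares below leave them out. For copper in wild type, 9% of 2-fold and 71.7% of 4-fold changes were recovered. The corresponding shares were 8% and 65% for copper in KO, 5% and 73% for KO against wild type untreated, and 14.1% and 66.7% for KO against wild type in copper. For the interaction they were 0% and 19%. Each simulation ran on 11051 genes and at most 5 unchanged genes were called. Means, depths and spreads came from the data, but a deviation shared by libraries of different groups was not simulated. The count of 5 therefore does not bound false calls from such a deviation. In the data 545 to 3721 genes were called per comparison, against 200 changed genes and the raised proteasome genes in a simulation. The shares recovered hold for the simulated counts and are not the power in the data.

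Alternatives fixed beforehand were relative log expression (RLE) factors, library totals with no further scaling, no filter, DESeq2 1.42.0, the replicate number as a block, leaving out each compared library in turn, the 6 compared libraries alone, and a 2-fold minimum. After seeing the data, a fit without 3 libraries that stood apart and a limma voom fit with a weight per library were added, and counts of calls without each library outside a comparison, since all 12 share the fit. Without the 3 libraries, ATP7B KO untreated replicate 3 was alone in its group in 3 of the 5 comparisons (copper in KO cells, KO against wild type untreated and the interaction). It was assumed there to vary like the other groups. Replicates of KO untreated cells agreed least of all groups, so p-values of those 3 comparisons in that fit may be too small. The 3 libraries were left out because they deviated, so the remaining spread may be understated in all 5 comparisons of that fit.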

Results

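The study compared the response to copper of liver-derived cells with and without the copper exporter ATP7B, and its title concerns autophagy as a survival mechanism in Wilson disease. Wild type libraries held 3561723 to 3829151 counts untreated and 1873703 to 2581954 in copper. ATP7B KO libraries held 976658 to 3277087 counts untreated and 2388597 to 2807634 in copper. Mitochondrially encoded genes took 2.97% to 3.81% of the counts in wild type untreated libraries and 5.82% to 9.46% in the other 9.

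ATP7B was counted in all groups. It was at 12.7, 13.1 and 12.3 CPM in wild type untreated replicates 1 to 3 and at 5.34, 3.92 and 3.87 CPM in wild type copper replicates 1 to 3. In KO cells it was at 9.01, 2.05 and 11.6 CPM untreated and at 3.92, 4.19 and 6.77 CPM in copper. ATP7B fell with copper in wild type cells (log2 fold change -1.51 ± 0.41 SE, adjusted p = 0.026). That call ended without any of wild type untreated replicates 1, 2 and 3 or wild type copper replicates 2 and 3 (adjusted p 0.077 to 0.10). In KO cells ATP7B was at -0.61 ± 0.42 with copper (adjusted p = 0.27), and passed the threshold without ATP7B KO untreated replicate 2 (adjusted p = 0.041) or without the 3 libraries that stood apart, named in the next paragraph (0.020). KO against wild type was at -0.75 ± 0.38 untreated (adjusted p = 0.15), and passed without ATP7B KO untreated replicate 3 (0.041). In copper it was at 0.15 ± 0.44 (adjusted p = 0.86). The position of the edit is not given in the sources used here, and a 3′ tag outside it would leave the transcript level uninformative about the KO label.

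The libraries did not group by design alone. Wild type copper replicate 1 and ATP7B KO untreated replicates 1 and 2 were at 23.9, 111 and 120.4 on the first principal component (44.2% of the variance), and the other 9 libraries were below 0. Log2 CPM of KO untreated replicates 1 and 2 were correlated across genes at 0.923 with each other and at 0.830 and 0.803 with replicate 3. Within KO copper the correlations were 0.982 to 0.983, within wild type untreated 0.988 to 0.990 and within wild type copper 0.916 to 0.976. The deviations of wild type copper replicate 1 and of KO untreated replicates 1 and 2 from the rest of their groups were correlated at 0.642 across 11051 genes, which are not independent replicates. The median shared deviation was -1.41 on the log2 scale for metallothioneins, -0.98 for ribosomal protein genes, -0.77 for nuclear-encoded respiratory chain genes, -0.69 for immediate early genes and 0.82 for replication-dependent histones. These 3 libraries are called the libraries that stood apart. Without them KO untreated replicate 3 was alone in its group, and was assumed to vary like the other groups. The correlations go against that assumption, since those within KO untreated ran lowest (0.803 to 0.923). Adjusted p-values from that fit that rest on this replicate may therefore be too small. Leaving libraries out because they deviated may also understate the spread in the other comparisons of that fit. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 1.85 to 52.1), so each library counted once.

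**Figure D1:**
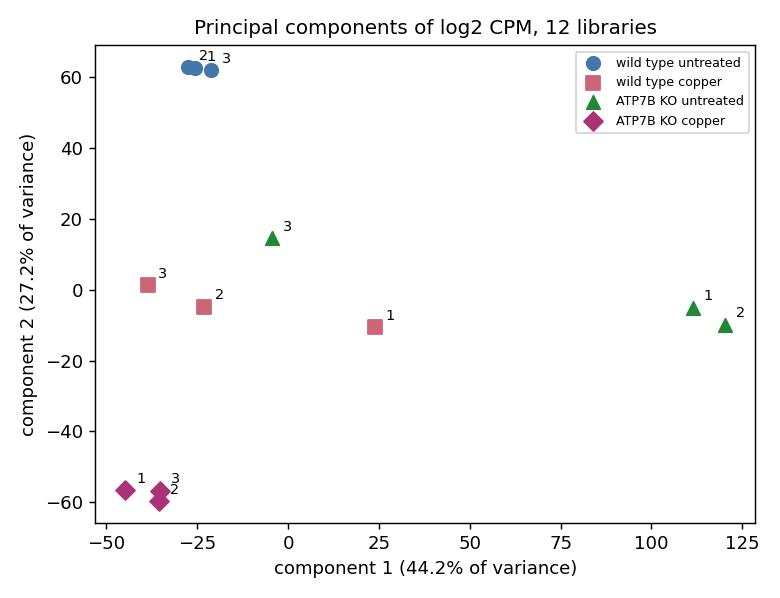
Principal components of log2 CPM of 11051 genes, with component 1 on the horizontal and component 2 on the vertical axis, both without units. Each point is a library and each digit its replicate number. ATP7B KO untreated replicates 1 and 2 lie at 111 and 120.4 on component 1, and wild type copper replicate 1 at 23.9.

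Copper in wild type cells raised metallothioneins, cytosolic heat shock proteins, antioxidant genes and immediate early genes, and lowered liver-secreted proteins and mitotic genes. MT1X, a metal-binding metallothionein, rose from 3.93 ± 0.97 to 277 ± 8.2 CPM (mean ± SD, n = 3; log2 fold change 6.15 ± 0.31 SE, adjusted p = 3.2e-07). HMOX1, the haem-degrading enzyme of the oxidative stress response, rose from 273 ± 19.9 to 4910 ± 1300 CPM (4.20 ± 0.35, adjusted p = 2.7e-05). CRYAB, a small heat shock protein, rose from 0.537 ± 0.021 to 38.2 ± 4.2 CPM. ALB, which encodes albumin, went from 6876 ± 57.0 to 3660 ± 166 CPM (-0.88 ± 0.19, adjusted p = 0.010). Of 11051 genes, 1648 were called, 910 of which rose and 738 fell. The share that rose, 55.2%, was 47.7% with no filter and 45.9% with limma voom, so the majority depended on the fit.

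In wild type cells 8 of 9 metallothioneins rose with copper (8 adjusted over the list alone, camera adjusted p = 1.7e-24, median log2 fold change 6.06), among them MT1F by 4.08 ± 0.36, MT1E by 4.61 ± 0.95 and MT2A by 3.85 ± 0.85. Leaving out wild type untreated replicate 1, 2 or 3 ended the MT2A call (adjusted p 0.0507 to 0.056). Of the cytosolic heat shock genes 15 of 25 rose (16 adjusted over the list alone, adjusted p = 8.4e-19), including HSPH1 by 4.25 ± 0.27 and the co-chaperone CHORDC1 by 3.64 ± 0.36. Immediate early genes, transcription factors and phosphatases induced quickly by stimuli, rose in 11 of 17 cases (13 adjusted over the list alone, adjusted p = 8.8e-19), including EGR1 by 4.88 ± 0.21, FOSB by 5.25 ± 0.32, FOS by 5.25 ± 0.51 and JUN by 1.89 ± 0.18. Targets of the antioxidant factor NRF2 rose in 8 of 28 cases (10 adjusted over the list alone, adjusted p = 3.3e-08), including the cystine transporter SLC7A11 by 3.37 ± 0.24, the thioredoxin reductase TXNRD1 by 2.52 ± 0.19 and the glutathione synthesis subunit GCLM by 3.51 ± 0.31. Genes of ATF4 and the integrated stress response rose in 11 of 25 cases (13 adjusted over the list alone, adjusted p = 2.2e-07), including SESN2 by 2.24 ± 0.18, ATF3 by 2.94 ± 0.30 and PPP1R15A by 2.56 ± 0.30. Proteasome genes rose in 14 of 30 cases (15 adjusted over the list alone, adjusted p = 1.4e-07), including PSMD12 by 1.52 ± 0.16 and PSMD14 by 1.90 ± 0.29. Mitochondrially encoded genes rose in 10 of 13 cases (11 adjusted over the list alone, adjusted p = 2e-10), including MT-ND1 by 1.72 ± 0.19 and MT-CO1 by 2.14 ± 0.28. NF-kappaB and cytokine genes rose in 6 of 11 cases (7 adjusted over the list alone, adjusted p = 0.0035), including RELB by 1.58 ± 0.30. The chemokine gene CXCL8 had 29 counts against 3 (16.0-fold, 95% counting interval 4.96 to 82.2).

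Autophagy genes moved in both directions in wild type cells given copper, with 6 of 42 rising and 3 falling (7 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.0074, direction up). SQSTM1, an autophagy receptor that is also an NRF2 target, rose from 155 ± 8.6 to 1196 ± 349 CPM (2.98 ± 0.37, adjusted p = 0.00046). Autophagosome genes and receptors that rose included GABARAPL1 by 2.03 ± 0.28, TAX1BP1 by 1.09 ± 0.16 and ATG2A by 1.03 ± 0.21. MAP1LC3B, which encodes the autophagosome protein LC3B, rose by 1.32 ± 0.36 (adjusted p = 0.030). Its call ended without wild type untreated replicates 1, 2 or 3 or wild type copper replicates 2 or 3 (adjusted p 0.089 to 0.11). TFEB, a transcription factor of lysosomal genes, was at -0.14 ± 0.42 (adjusted p = 0.86). Lysosome genes rose in 2 and fell in 2 of 36 cases (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.98).

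Hepatocyte secreted proteins and regulators fell in 16 of 32 cases with copper in wild type cells (24 adjusted over the list alone, camera adjusted p = 4.7e-12), with the apolipoprotein APOC3 at -2.61 ± 0.33, the thyroxine carrier TTR at -2.29 ± 0.32 and the fibrinogen chain FGA at -1.53 ± 0.20. The fetal counterpart of albumin was called too, with AFP at -1.51 ± 0.33. The ALB and AFP calls ended without wild type copper replicate 2 (adjusted p = 0.0512 and 0.0535). Mitotic G2/M genes fell in 16 of 30 cases (22 adjusted over the list alone, adjusted p = 2.1e-12), with the centromere protein CENPF at -2.05 ± 0.23 and the mitotic kinase PLK1 at -1.83 ± 0.26. Fatty acid oxidation genes fell in 10 of 18 cases (12 adjusted over the list alone, adjusted p = 2.6e-06), with the coactivator PPARGC1A at -2.11 ± 0.34 and the lipase inhibitor ANGPTL4 at -2.26 ± 0.49, whose call ended without wild type copper replicate 2 (adjusted p = 0.059). Cholesterol synthesis genes fell in 6 of 24 cases (8 adjusted over the list alone, adjusted p = 0.0019). Fatty acid and triglyceride synthesis genes fell in 4 and rose in 1 of 16 cases (1 rose and 8 fell adjusted over the list alone, adjusted p = 0.011), with the desaturase SCD at -1.74 ± 0.37. The list calls given so far for wild type cells held with an estimated correlation.

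Another 4 lists were called lower with copper in wild type cells and lost the call with an estimated correlation. Endoplasmic reticulum chaperones fell in 4 of 21 cases (7 adjusted over the list alone, camera adjusted p = 0.0074), with the disulfide isomerase PDIA4 at -1.11 ± 0.22, and had adjusted p = 0.20 with an estimated correlation. Iron homeostasis genes fell in 5 and rose in 1 of 11 cases (1 rose and 5 fell adjusted over the list alone, adjusted p = 0.032), with adjusted p = 0.083 with an estimated correlation and 0.058 without wild type copper replicate 2. HAMP, which encodes the iron-regulating hormone hepcidin, was at -3.10 ± 0.59. Nuclear-encoded respiratory chain genes fell in 1 of 34 cases (0 adjusted over the list alone, adjusted p = 0.0043, adjusted p = 0.45 with an estimated correlation). Ribosomal protein genes called were 0 of 52 with edgeR, 5 at an unadjusted p under 0.05, 4 with DESeq2 and 32 with limma voom. The list passed (0 adjusted over the list alone, adjusted p = 0.020, adjusted p = 0.66 with an estimated correlation and 0.0517 without wild type copper replicate 1). Respiratory chain and ribosomal protein genes were also low in the libraries that stood apart, one of which is wild type copper replicate 1, with median shared deviations of -0.77 and -0.98. Without those libraries their medians went from -0.52 to -0.35 and from -0.45 to -0.25.

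The 10 genes with the largest rise in wild type cells were GADD45G, HSPA6, MT1B, MT1M, RRAD, ARC, MT1HL1, VGF, MT1H and LBH. GADD45G, a DNA damage-inducible gene, the heat shock gene HSPA6, MT1B and MT1HL1 had 0 untreated counts and were at least 188-fold, 174-fold, 168-fold and 45.3-fold higher with copper. RRAD, a small GTPase, rose from 0.539 ± 0.53 to 199.6 ± 22.3 CPM. MT1M had 734 counts against 1 (1216-fold, 95% counting interval 218 to 48100), ARC 263 against 1 (436-fold, 95% counting interval 77.5 to 17270), VGF 180 against 2 (149-fold, 95% counting interval 40.7 to 1241), MT1H 144 against 2 (119-fold, 95% counting interval 32.4 to 994) and LBH 74 against 1 (123-fold, 95% counting interval 21.3 to 4907). The 10 with the largest fall were LEAP2, SOCS1, CLDN14, MMP11, MAB21L4, KANK4, HAMP, MIXL1, TMEM121 and SERPINA7, with log2 fold changes from -4.09 to -2.98. LEAP2 encodes a liver peptide and SOCS1 a brake on cytokine signalling.

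Of 19 tested zinc transporter genes 4 fell and 1 rose with copper in wild type cells (2 rose and 6 fell adjusted over the list alone, camera adjusted p = 0.0523), with SLC39A14 at -1.60 ± 0.22. The zinc list passed without wild type untreated replicate 3 or wild type copper replicate 3 (adjusted p = 0.0445 and 0.037), with relative log expression factors (0.0482) and with no filter (0.0094). The zinc exporter SLC30A1 was at 1.18 ± 0.43 (adjusted p = 0.084), and passed the threshold without the libraries that stood apart (2.4e-07). Of 15 copper transport genes 2 fell (2 adjusted over the list alone, adjusted p = 0.33), ATP7B and ceruloplasmin (CP), the main copper protein of plasma, at -1.36 ± 0.29 (adjusted p = 0.0085). The copper importer SLC31A1 was at 0.08 ± 0.20 (adjusted p = 0.83). Pro-apoptotic genes rose in 4 of 26 cases (4 adjusted over the list alone, adjusted p = 0.064), including PMAIP1 by 3.47 ± 0.53. That list passed without wild type untreated replicate 3 (adjusted p = 0.0479) and with no filter (0.038). Among genes of drug and bile acid metabolism 2 rose and 2 fell of 12 (adjusted p = 0.41), with the sulfotransferase SULT2A1 at -2.46 ± 0.27. The count of 1648 calls became 4784 without the libraries that stood apart, of which 1645 were among the first. It became 737, 734 and 812 without wild type untreated replicates 1, 2 and 3, and 1052 and 846 without wild type copper replicates 1 and 2. All 12 libraries share the fit, and without ATP7B KO untreated replicate 3, which is not compared here, it became 3779.

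In ATP7B KO cells copper raised metallothioneins, heat shock proteins, immediate early genes, proteasome genes and autophagy genes, and lowered liver-secreted proteins and lipid genes. MT1X rose from 3.61 ± 2.3 to 143 ± 2.1 CPM (log2 fold change 5.30 ± 0.32, adjusted p = 1.8e-06). CRYAB rose from 1.11 ± 0.25 to 179.7 ± 7.9 CPM and HMOX1 from 1053 ± 390.4 to 6435 ± 123 CPM (2.71 ± 0.33, adjusted p = 0.00015). MAP1LC3B rose from 40.4 ± 24.5 to 343 ± 30.7 CPM (3.19 ± 0.39, adjusted p = 0.00017). Copper called 3721 of 11051 genes in KO cells, 1675 of which rose and 2046 fell.

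Of the tested metallothioneins 9 of 9 rose with copper in KO cells (9 adjusted over the list alone, camera adjusted p = 1.7e-16, median log2 fold change 5.95, or 5.73 with 2 members without untreated counts set to their bound), including MT1G by 6.94 ± 0.79, MT1F by 4.77 ± 0.37, MT1E by 5.73 ± 1.01 and MT2A by 5.95 ± 0.94. Heat shock genes rose in 16 of 25 cases (17 adjusted over the list alone, adjusted p = 3.5e-17), including the co-chaperone BAG3 by 4.33 ± 0.34 and HSPH1 by 3.25 ± 0.26. Immediate early genes rose in 15 of 17 cases and fell in 2 (15 rose and 2 fell adjusted over the list alone, adjusted p = 1e-15), including EGR1 by 3.47 ± 0.22 and JUN by 2.22 ± 0.18, and FOSB had 414 counts against 2 (153-fold, 95% counting interval 42.1 to 1268). Proteasome genes rose in 22 of 30 cases (23 adjusted over the list alone, adjusted p = 4.9e-10), including PSMD12 by 1.95 ± 0.17 and PSMD1 by 1.89 ± 0.19. NRF2 targets rose in 14 and fell in 2 of 28 cases (17 rose and 2 fell adjusted over the list alone, adjusted p = 9.8e-06), including SLC7A11 by 3.35 ± 0.24, TXNRD1 by 2.21 ± 0.19 and GCLM by 2.29 ± 0.29. Genes of ATF4 and the integrated stress response rose in 9 and fell in 3 of 25 cases (12 rose and 3 fell adjusted over the list alone, adjusted p = 0.00022), including SESN2 by 2.14 ± 0.18, PPP1R15A by 3.53 ± 0.32 and the asparagine synthetase ASNS by 2.77 ± 0.34. NF-kappaB and cytokine genes rose in 6 and fell in 1 of 11 cases (7 rose and 1 fell adjusted over the list alone, adjusted p = 0.00058), including BIRC3 by 2.12 ± 0.30, with CXCL8 at 171 counts against 2 (63.2-fold, 95% counting interval 17.2 to 526). The NF-kappaB call ended without ATP7B KO untreated replicate 3 (adjusted p = 0.056).

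Autophagy genes rose in 14 and fell in 5 of 42 cases in KO cells given copper (14 rose and 6 fell adjusted over the list alone, camera adjusted p = 0.0038). The call held with an estimated correlation (adjusted p = 0.019) and ended without ATP7B KO untreated replicate 3 (0.060). Members that rose included GABARAPL1 by 3.40 ± 0.30, TAX1BP1 by 1.59 ± 0.17, the autophagosome membrane protein VMP1 by 1.59 ± 0.19 and SQSTM1 by 1.40 ± 0.35. The SQSTM1 call ended in a fit of the 6 compared libraries alone (adjusted p = 0.062). Lysosome genes rose in 13 and fell in 3 of 36 cases (13 rose and 3 fell adjusted over the list alone, adjusted p = 0.0024, adjusted p = 0.23 with an estimated correlation). The list was low in the libraries that stood apart (median shared deviation -0.49), and without them its median went from 0.76 to 0.35 (adjusted p = 0.023). The proton pump subunits ATP6V1D and ATP6V1C1 rose by 2.18 ± 0.30 and 1.34 ± 0.25 and the protease CTSL by 1.52 ± 0.25, while TFEB was at -2.54 ± 0.51 (adjusted p = 0.0031). Genes of mTORC1, the kinase complex that restrains autophagy, and its lysosomal regulators rose in 4 and fell in 2 of 25 cases (4 rose and 2 fell adjusted over the list alone, adjusted p = 0.53), including RRAGC by 1.72 ± 0.20 and LAMTOR3 by 2.31 ± 0.35.

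Hepatocyte secreted proteins and regulators fell in 20 of 32 cases in KO cells given copper (21 adjusted over the list alone, camera adjusted p = 1.2e-08), with the fibrinogen chains FGA at -2.72 ± 0.21 and FGG at -3.02 ± 0.26. ALB was at -1.16 ± 0.19 (adjusted p = 0.0010) and AFP at -0.51 ± 0.32 (adjusted p = 0.23), which passed without the libraries that stood apart (0.018). Fatty acid oxidation genes fell in 10 and rose in 1 of 18 cases (1 rose and 12 fell adjusted over the list alone, adjusted p = 0.00034), with the peroxisomal enzyme EHHADH at -2.70 ± 0.33 and the lipid-sensing receptor PPARA at -1.83 ± 0.27. Fatty acid and triglyceride synthesis genes fell in 7 and rose in 1 of 16 cases (1 rose and 8 fell adjusted over the list alone, adjusted p = 0.0014), with GPAM at -2.10 ± 0.19 and PNPLA3 at -4.18 ± 0.46. Cholesterol synthesis genes fell in 9 and rose in 1 of 24 cases (1 rose and 12 fell adjusted over the list alone, adjusted p = 0.0086), with the squalene oxidase SQLE at -1.42 ± 0.16. That call was lost with an estimated correlation (adjusted p = 0.080) and without ATP7B KO untreated replicate 3 (0.16).

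G2/M genes fell in 10 of 30 cases in KO cells given copper (10 adjusted over the list alone, camera adjusted p = 0.033), with the proliferation marker MKI67 at -1.82 ± 0.21 and CENPF at -1.66 ± 0.22. This call was lost with an estimated correlation (adjusted p = 0.43), without ATP7B KO untreated replicate 3 (0.75), without ATP7B KO copper replicate 3 (0.058) and with the replicate number as a block (0.0542). In the fit without the libraries that stood apart the list median went from -0.49 to -1.005. Mitochondrially encoded genes rose in 6 of 13 cases (9 rose and 1 fell adjusted over the list alone, adjusted p = 0.016, adjusted p = 0.39 with an estimated correlation), including MT-ND1 by 1.10 ± 0.19. Ribosomal protein genes rose in 7 and fell in 1 of 52 cases (0 rose and 0 fell adjusted over the list alone, adjusted p = 0.00047). That call was lost with an estimated correlation (adjusted p = 0.49) and without the libraries that stood apart (0.23), in which this list was low (median shared deviation -0.98). Targets of p53 fell in 8 and rose in 1 of 23 cases (4 rose and 8 fell adjusted over the list alone, adjusted p = 0.29), with SESN1 at -2.27 ± 0.31, ZMAT3 at -1.71 ± 0.24 and the pro-apoptotic gene BAX at -2.25 ± 0.45. The list passed without the libraries that stood apart (0.028). Pro-apoptotic genes rose in 6 and fell in 4 of 26 cases (7 rose and 4 fell adjusted over the list alone, adjusted p = 0.70), including PMAIP1 by 3.50 ± 0.54. CP was at -2.80 ± 0.32 (adjusted p = 0.00011) and SLC31A1 at 0.13 ± 0.20 (adjusted p = 0.64).

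The 10 largest rises with copper in KO cells were those of MT1B, ARC, GADD45G, HSPA6, MT1M, GFPT2, PLK5, LSMEM1, TENT5C and MT1H. MT1B, ARC, GFPT2, PLK5, LSMEM1, TENT5C and MT1H had 0 untreated counts and were at least 308-fold, 144-fold, 36.0-fold, 24.1-fold, 22.4-fold, 21.9-fold and 19.96-fold higher with copper. GADD45G had 887 counts against 1 (656-fold, 95% counting interval 117 to 25920), HSPA6 851 against 1 (629-fold, 95% counting interval 113 to 24870) and MT1M 1206 against 2 (446-fold, 95% counting interval 123 to 3684). The 10 largest falls were those of TUBA4B, CLDN14, PRR15L, ONECUT1, HP, MIXL1, LEAP2, TNFSF10, NRTN and CASKIN1. LEAP2 was at -4.76 ± 0.37, HP, which encodes haptoglobin, at -4.98 ± 0.77 and ONECUT1, a liver transcription factor, at -5.15 ± 0.80. The CASKIN1 call (46 counts untreated against 3, 20.8-fold, 95% counting interval 6.67 to 104) ended without the libraries that stood apart (adjusted p = 0.37), without ATP7B KO untreated replicate 1 (0.062) and without ATP7B KO copper replicate 3 (0.0511). SLC30A1 rose by 1.59 ± 0.45 (adjusted p = 0.017). That call ended without ATP7B KO untreated replicates 1 or 2 or ATP7B KO copper replicate 1 (adjusted p 0.0506 to 0.0535) and in a fit of the 6 compared libraries alone (0.062). With library totals as the only scaling, 34.2% in place of 45.0% of the calls in KO cells rose, and the median log2 fold change of all genes moved from 0.01 to -0.12. The share was 51.5% without ATP7B KO untreated replicate 3 and 52.0% with limma voom. The count of 3721 became 4739 without the libraries that stood apart, 6635 without ATP7B KO untreated replicate 3 and 2372 without ATP7B KO copper replicate 1.

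**Figure D2:**
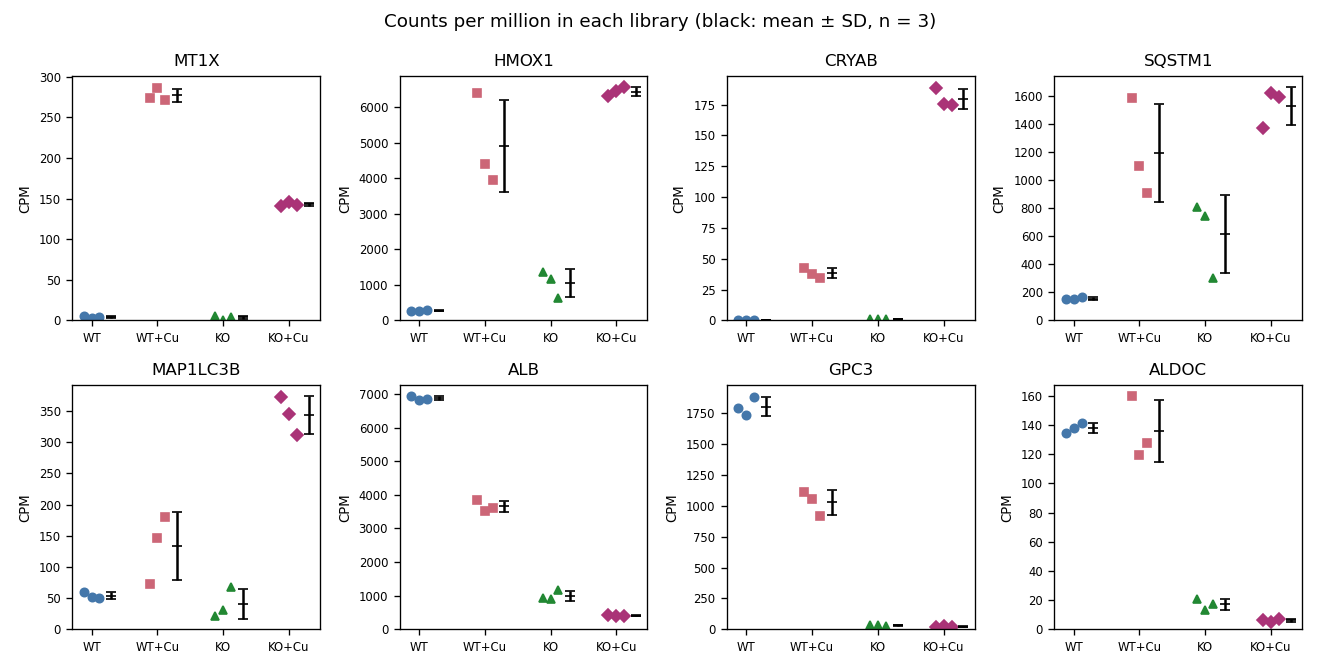
CPM on the vertical axis for 8 genes in wild type (WT) and ATP7B KO (KO) cells, untreated or with copper (Cu), each point a library and each black bar the mean ± SD of 3 libraries. MT1X and CRYAB are low in every untreated library, and GPC3 and ALDOC are lower in every KO library than in every wild type library.

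The copper responses of wild type and KO cells overlapped. Of 910 genes that rose in wild type cells and 1675 that rose in KO cells, 487 rose in both, against 137.9 for independent lists (one-sided Fisher's exact test across genes, p = 3.5e-180). Of 738 and 2046 that fell, 366 fell in both, against 136.6 (same exact test, p = 9.8e-89). Called in opposite directions were 22 genes that rose and 11 that fell in wild type cells. The copper comparisons share no library, but they share the filter and the estimate of each gene's spread. Genes with little spread can therefore be called in both more often than independent lists allow. The exact tests ignore this and count genes as independent. The log2 fold changes of the copper comparisons were correlated across 11051 genes at 0.430 (Pearson) and 0.235 (Spearman), with genes not being independent replicates. Shared calls in 1 direction numbered 853, and 2880 without the libraries that stood apart. They numbered 484, 488 and 498 without wild type untreated replicates 1, 2 and 3, 526 without wild type copper replicate 2, and 1342 without ATP7B KO untreated replicate 3.

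**Figure D3:**
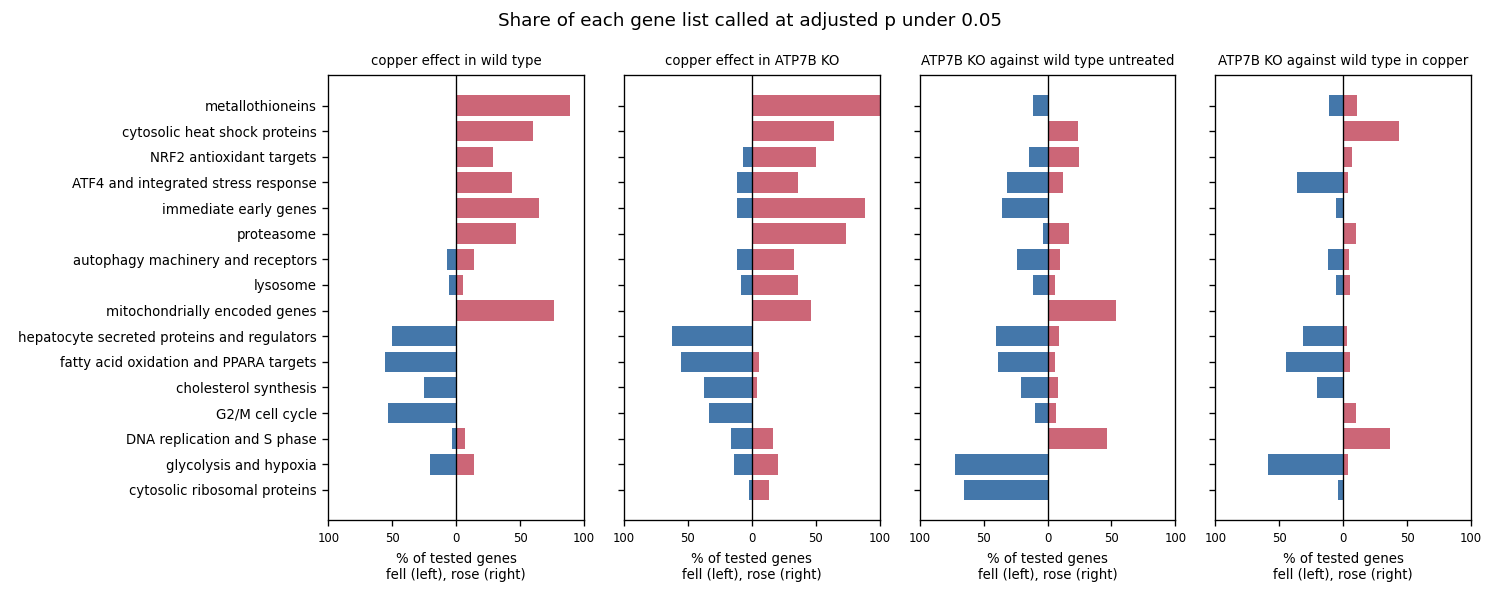
Percent of tested genes in 16 of the 34 lists that were called lower (left of 0) or higher (right of 0) at an adjusted p under 0.05, in 4 comparisons. Metallothioneins rose in 8 of 9 and 9 of 9 cases with copper, and glycolysis and hypoxia genes were lower in 21 and 17 of 29 cases in KO cells.

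Without added copper, ATP7B KO cells had lower glycolysis and hypoxia genes, lower albumin and higher DNA replication genes than wild type cells. Glycolysis and hypoxia genes were lower in 21 of 29 cases (22 adjusted over the list alone, camera adjusted p = 5.9e-17, adjusted p = 0.00055 with an estimated correlation), with a median shared deviation of -0.04 in the libraries that stood apart. ALDOC, a glycolytic aldolase, was at 138 ± 3.4 CPM in wild type and 17.2 ± 3.7 CPM in KO cells (log2 fold change -3.12 ± 0.23, adjusted p = 9.1e-06). The hypoxia-induced repressor BHLHE40 was at -4.22 ± 0.31, the collagen hydroxylase P4HA1 at -2.49 ± 0.22 and the enolase ENO2 at -2.23 ± 0.20. ALB was at 6876 ± 57.0 CPM in wild type and 999.7 ± 155 CPM in KO cells (-2.91 ± 0.21, adjusted p = 8.7e-06). AFP was at -1.64 ± 0.33. Of 11051 genes 3521 were called, 1975 higher and 1546 lower in KO cells.

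DNA replication and S phase genes were higher in untreated KO cells in 14 of 30 cases (17 adjusted over the list alone, camera adjusted p = 0.00030, adjusted p = 0.023 with an estimated correlation), including MCM10 by 1.51 ± 0.22, CDC6 by 1.34 ± 0.20 and GINS3 by 2.14 ± 0.34. The hepatocyte list was lower in 13 and higher in 3 of 32 cases (4 higher and 14 lower adjusted over the list alone, adjusted p = 0.0072, adjusted p = 0.18 with an estimated correlation), with the serum protein AHSG at -2.06 ± 0.27. Ribosomal protein genes were lower in 34 of 52 cases (43 adjusted over the list alone, adjusted p = 1.8e-09, adjusted p = 0.35 with an estimated correlation), with RPS25 at -1.52 ± 0.32 and RPL32 at -0.87 ± 0.17. The RPL32 call ended in a fit of the 6 compared libraries alone (adjusted p = 0.060). Ribosomal protein genes were low in the libraries that stood apart (median shared deviation -0.98), without which the medians went from -1.30 to -0.56 for this list and from -0.70 to -0.44 for the hepatocyte list. Mitochondrially encoded genes were higher in 7 of 13 cases (8 adjusted over the list alone, adjusted p = 0.0039, adjusted p = 0.35 with an estimated correlation), including MT-ATP6 by 1.66 ± 0.27 and MT-CO3 by 2.73 ± 0.45. Nuclear-encoded respiratory chain genes were lower in 8 and higher in 1 of 34 cases (1 higher and 8 lower adjusted over the list alone, adjusted p = 0.0031). They had a median shared deviation of -0.77 in the libraries that stood apart, and their call was lost with an estimated correlation (adjusted p = 0.47) and without those libraries (0.089).

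Targets of p53 were higher in 10 and lower in 2 of 23 cases in untreated KO cells (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.014), with FDXR at 1.98 ± 0.19 and TP53I3 at 1.76 ± 0.29. Immediate early genes were lower in 6 of 17 cases (6 adjusted over the list alone, adjusted p = 0.018), with the phosphatase DUSP1 at -3.17 ± 0.64 and FOSL2 at -1.95 ± 0.29. They were low in the libraries that stood apart (median shared deviation -0.69). Fatty acid oxidation genes were lower in 7 and higher in 1 of 18 cases (1 higher and 8 lower adjusted over the list alone, adjusted p = 0.033), with the lipid droplet protein PLIN2 at -1.80 ± 0.23. These 3 calls were lost with an estimated correlation (adjusted p = 0.19, 0.18 and 0.18) and without ATP7B KO untreated replicate 3 (adjusted p = 0.28, 0.075 and 0.075). The fatty acid oxidation median went from -0.64 to -0.34 without the libraries that stood apart.

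Autophagy genes were lower in 10 and higher in 4 of 42 cases in untreated KO cells (4 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.074). The list passed with no filter (0.0057). Without the libraries that stood apart its median went from -0.25 to -0.15. The mitophagy receptors BNIP3 and BNIP3L were at -2.64 ± 0.20 and -3.14 ± 0.43 and the receptor NBR1 at -1.86 ± 0.28. SQSTM1 and HMOX1 were higher by 1.89 ± 0.36 and 1.84 ± 0.32, while MAP1LC3B and TFEB were at -0.53 ± 0.37 and 0.20 ± 0.42 (adjusted p = 0.28 and 0.73). Without ATP7B KO untreated replicate 3, MAP1LC3B passed the threshold at -1.10 (adjusted p = 0.0099). Heat shock genes were higher in 6 of 25 cases (6 adjusted over the list alone, adjusted p = 0.15), including HSPH1 by 1.83 ± 0.25 and DNAJA1 by 1.85 ± 0.24. The heat shock median went from 0.30 to 0.53 without the libraries that stood apart. CP was at -1.76 ± 0.29 and SLC31A1 at -0.80 ± 0.20 (adjusted p = 0.0016 and 0.011). The SLC31A1 call ended in a fit of the 6 compared libraries alone (adjusted p = 0.078). Of 9 metallothioneins 1 was lower (0 adjusted over the list alone, adjusted p = 0.29), which was MT2A at -2.25 ± 0.80 (adjusted p = 0.0481). The list was low in the libraries that stood apart (median shared deviation -1.41). The MT2A call ended without any of wild type untreated replicates 1, 2 and 3 or ATP7B KO untreated replicates 1 and 2 (adjusted p 0.086 to 0.14), and with library totals as the only scaling (0.071) or in a fit of the 6 compared libraries alone (0.13).

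The 10 genes with the largest excess in untreated KO cells were LINC01996, RNF157, OLFML1, PLA2G2A, TUBA4B, ARSI, PRRG4, MUC20, HBE1 and NRGN. RNF157 was at 1.51 ± 0.36 CPM in wild type and 246 ± 60.3 CPM in KO cells, and PLA2G2A, a secreted phospholipase, at 3.46 ± 0.85 and 331 ± 72.1 CPM. LINC01996 had 0 wild type counts and was at least 45.1-fold higher in KO cells, and OLFML1 had 91 counts against 1 (179-fold, 95% counting interval 31.3 to 7133). Among the 10 with the largest deficit were EGLN3, BEX1, CDCA7L, ROBO4, GPC3, RHBDD1, EDN1, TNNI2 and IGFBP1. GPC3, a cell surface proteoglycan of liver tumours, was at 1806 ± 75.3 CPM in wild type and 32.4 ± 4.7 CPM in KO cells (log2 fold change -5.93 ± 0.24, adjusted p = 7e-08). EGLN3, an oxygen-sensing hydroxylase, had 0 KO counts and was at least 40.1-fold lower. With library totals as the only scaling, 69.4% in place of 56.1% of the calls were higher in KO cells, and the median log2 fold change of all genes moved from -0.02 to 0.12. The share was 48.9% without ATP7B KO untreated replicate 3, 48.7% without the libraries that stood apart and 48.5% with limma voom, so the majority was not the same in every fit. The count of 3521 became 4132 without the libraries that stood apart. It became 2058, 2104 and 2231 without wild type untreated replicates 1, 2 and 3, 2289 without ATP7B KO untreated replicate 1 and 6738 without ATP7B KO untreated replicate 3.

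In copper, ATP7B KO cells had lower glycolysis and hypoxia genes and lower albumin than wild type cells, and higher heat shock and DNA replication genes. Glycolysis and hypoxia genes were lower in 17 and higher in 1 of 29 cases (2 higher and 19 lower adjusted over the list alone, camera adjusted p = 9e-13, adjusted p = 0.00084 with an estimated correlation), with ALDOC at -4.47 ± 0.24, ENO2 at -1.75 ± 0.19 and BHLHE40 at -2.23 ± 0.27. CRYAB was at 38.2 ± 4.2 CPM in wild type and 179.7 ± 7.9 CPM in KO cells (log2 fold change 2.20 ± 0.18, adjusted p = 3e-05). ALB was at 3660 ± 166 and 410.4 ± 13.6 CPM (-3.19 ± 0.21, adjusted p = 4.8e-06). Of 11051 genes 1525 were called, 638 higher and 887 lower in KO cells. The share that was higher, 41.8%, was 53.4% with limma voom, so the majority turned in that fit.

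Cytosolic heat shock genes were higher in KO cells in copper in 11 of 25 cases (12 adjusted over the list alone, camera adjusted p = 1.9e-07), including DNAJB1 by 2.26 ± 0.34 and BAG3 by 1.58 ± 0.29. The hepatocyte list was lower in 10 and higher in 1 of 32 cases (1 higher and 11 lower adjusted over the list alone, adjusted p = 7.4e-06), with FGA at -1.57 ± 0.20 and the iron carrier TF at -1.42 ± 0.20. DNA replication genes were higher in 11 of 30 cases (13 adjusted over the list alone, adjusted p = 4.7e-06), including GINS3 by 1.91 ± 0.33, CDC6 by 1.06 ± 0.19 and RFC5 by 1.46 ± 0.26. The heat shock, hepatocyte and DNA replication calls held with an estimated correlation (adjusted p = 0.027, 0.030 and 0.0071). Fatty acid oxidation genes were lower in 8 and higher in 1 of 18 cases (2 higher and 10 lower adjusted over the list alone, adjusted p = 0.0015, adjusted p = 0.0547 with an estimated correlation), with PPARA at -2.30 ± 0.27 and PLIN2 at -1.22 ± 0.23. Proteasome genes were higher in 3 of 30 cases (3 adjusted over the list alone, adjusted p = 0.013, adjusted p = 0.21 with an estimated correlation), and their median went from 0.48 to 0.28 without the libraries that stood apart.

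A further 4 lists passed in this comparison and lost the call with an estimated correlation. Cholesterol synthesis genes were lower in KO cells in copper in 5 of 24 cases (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.029, adjusted p = 0.15 with an estimated correlation), with SQLE at -1.22 ± 0.16. Their call ended without wild type copper replicate 3 (0.0503). ATF4 genes were lower in 9 and higher in 1 of 25 cases (2 higher and 9 lower adjusted over the list alone, adjusted p = 0.043, adjusted p = 0.19 with an estimated correlation), with the serine synthesis enzyme PSPH at -1.42 ± 0.20 and DDIT4 at -1.86 ± 0.39. The ATF4 call ended without wild type copper replicate 3 or ATP7B KO copper replicates 2 or 3 (adjusted p = 0.091, 0.061 and 0.064). Fatty acid and triglyceride synthesis genes were lower in 5 and higher in 1 of 16 cases (2 higher and 6 lower adjusted over the list alone, adjusted p = 0.043, adjusted p = 0.15 with an estimated correlation), with AGPAT2 at -3.46 ± 0.36. That call ended without wild type copper replicate 3 or ATP7B KO copper replicate 2 (adjusted p = 0.082 and 0.070). G2/M genes were higher in 3 of 30 cases (3 adjusted over the list alone, adjusted p = 0.0497, adjusted p = 0.49 with an estimated correlation). Their call ended without wild type copper replicates 1 or 2 or ATP7B KO copper replicate 2 (adjusted p = 0.079, 0.082 and 0.070) and without the libraries that stood apart (0.074).

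Autophagy genes were lower in 5 and higher in 2 of 42 cases in KO cells in copper (2 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.31), with BNIP3 at -1.85 ± 0.19, WIPI1 at -1.61 ± 0.23 and ATG9A at -1.36 ± 0.20. MAP1LC3B was at 133 ± 54.5 CPM in wild type and 343 ± 30.7 CPM in KO cells (1.34 ± 0.36, adjusted p = 0.029) and TFEB at -2.20 ± 0.52 (adjusted p = 0.015). The MAP1LC3B call ended without wild type copper replicates 1 or 2 or any ATP7B KO copper replicate (adjusted p 0.066 to 0.11). The TFEB call ended without wild type copper replicate 1 or ATP7B KO copper replicates 1 or 2 (adjusted p 0.05003 to 0.064). HMOX1 and SQSTM1 were at 0.35 ± 0.31 and 0.31 ± 0.34 (adjusted p = 0.48 and 0.58). Both passed without the libraries that stood apart at 0.54 and 0.52 (adjusted p = 3.7e-06 and 2.4e-05). The spread in that fit may be understated, since those libraries were left out for deviating. AFP was at -0.64 ± 0.32 (adjusted p = 0.20), and passed without those libraries (0.023).

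Among 9 metallothioneins MT1X was lower in KO cells in copper at -0.99 ± 0.24 and MT1B higher at 1.88 ± 0.38 (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.79). The MT1X call ended without wild type copper replicate 2 or any ATP7B KO copper replicate (adjusted p 0.058 to 0.080). The MT1B call ended without wild type copper replicate 2 or ATP7B KO copper replicates 1 or 3 (adjusted p 0.0508 to 0.062). CP was at -3.20 ± 0.32 (adjusted p = 0.00012). SLC31A1 was at -0.75 ± 0.20 (adjusted p = 0.026). Its call ended without wild type copper replicates 1 or 3 or any ATP7B KO copper replicate (adjusted p 0.065 to 0.12) and with no filter (0.065). The largest excesses in KO cells were those of SYNPO, RNF157, PLA2G2A, HBE1 and MSRB3, and the largest deficits those of RHBDD1, EGLN3, BEX1, GPC3 and IL21R. GPC3 was at -5.55 ± 0.24, PLA2G2A at 5.13 ± 0.31 and HBE1, an embryonic globin, at 4.80 ± 0.42. The count of 1525 became 4527 without the libraries that stood apart, of which 1522 were among the first. It became 950 and 880 without wild type copper replicates 1 and 2, and 675, 767 and 729 without ATP7B KO copper replicates 1, 2 and 3. Without ATP7B KO untreated replicate 3, which is not compared here, it became 3561.

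Other lists were tested in the same way. Protein lipoylation and iron-sulfur assembly genes fell in 2 of 18 cases with copper in wild type cells and rose in 3 and fell in 2 of 18 in KO cells (camera adjusted p = 0.088 and 0.88). In wild type cells that list passed without wild type untreated replicate 3 (adjusted p = 0.0489), without the libraries that stood apart (0.0448) and with no filter (0.0054). Anti-apoptotic genes rose in 1 of 11 cases in wild type cells, and rose in 4 and fell in 2 of 11 in KO cells (adjusted p = 0.61 and 0.14). Replication-dependent histones rose in 1 and fell in 5 of 10 cases with copper in KO cells (adjusted p = 0.11, and 0.023 without ATP7B KO untreated replicate 3), and had a median shared deviation of 0.82 in the libraries that stood apart. Genes of drug and bile acid metabolism were higher in 5 and lower in 2 of 12 cases in untreated KO cells (adjusted p = 0.074, and 0.018 with no filter), with the glutathione transferase GSTA1 at 3.39 ± 0.44 and the nuclear receptor NR1I2 at 2.78 ± 0.39.

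Markers of other cell types did not pass as lists in untreated KO against wild type cells. Cholangiocyte and progenitor markers were higher in 5 and lower in 1 of 10 cases (adjusted p = 0.80), with the keratins KRT23 at 2.09 ± 0.33 and KRT19 at 1.06 ± 0.18 and the GPC3 deficit. Mesenchymal and fibroblast markers were higher in 2 and lower in 2 of 12 cases (adjusted p = 0.70), and leukocyte markers higher in 1 and lower in 1 of 5 (adjusted p = 0.83). LYVE1, the 1 endothelial marker tested, had 6 counts in untreated KO libraries and 0 in wild type (at least 3.93-fold, adjusted p = 0.025). The LYVE1 call ended without any of wild type untreated replicates 1, 2 and 3 or ATP7B KO untreated replicate 3 (adjusted p 0.059 to 0.13). In copper, cholangiocyte and progenitor markers were lower in KO cells in 3 of 10 cases (3 higher and 3 lower adjusted over the list alone, adjusted p = 0.064). That list passed as lower without wild type copper replicate 1 (0.035) and without the libraries that stood apart (0.00032), where 4 members were higher and 4 lower. Leukocyte markers were higher in 1 and lower in 2 of 5 cases and mesenchymal markers higher in 1 of 12 (adjusted p = 0.46 and 0.58). With copper, cholangiocyte and progenitor markers rose in 4 and fell in 2 of 10 cases in wild type cells and rose in 2 and fell in 4 in KO cells (adjusted p = 0.30 and 0.40). Their difference of the copper effects had adjusted p = 0.091, and passed as more negative with no filter (0.0475) and without the libraries that stood apart (0.00010). Leukocyte markers rose in 1 and fell in 2 of 5 cases with copper in wild type cells and fell in 2 of 5 in KO cells (adjusted p = 0.35 and 0.29).

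The median, mean and set test of a list differed in sign only where the list was not called. This was so for p53 targets, DNA replication and mesenchymal markers with copper in wild type cells, for copper transport, zinc transporters and mesenchymal markers with copper in KO cells, and for NRF2 targets and NF-kappaB genes in untreated KO against wild type cells. In copper it was so for metallothioneins, copper transport, pro-apoptotic, immediate early, lipoylation and ribosomal protein genes in KO against wild type cells. For the difference of the copper effects it was so for mTORC1, NF-kappaB, DNA replication, hepatocyte, cholesterol synthesis and leukocyte genes.

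The difference of the copper effects between KO and wild type cells was called for 545 of 11051 genes, 139 with a more positive and 406 with a more negative copper effect in KO cells. EDN1, which encodes a vasoconstrictor peptide, had 174 counts untreated and 20 with copper in wild type cells, and 2 and 82 in KO cells (log2 difference 7.26 ± 0.65, adjusted p = 0.00083). SNAI1, a transcription factor of epithelial-mesenchymal transition, was at 2.14 ± 0.48 CPM untreated and 8.99 ± 5.3 CPM with copper in wild type cells, and at 0.693 ± 1.2 and 56.9 ± 12.47 CPM in KO cells, where the 3 untreated libraries held 3 counts in all. CCN1, CD9 and CCNG2 also had more positive copper effects in KO cells, and IL21R, ARSI, NRTN, ONECUT1 and CES1 more negative ones. The co-chaperones BAG3, DNAJB1 and DNAJB4 differed by 1.81 ± 0.43, 1.88 ± 0.47 and 2.32 ± 0.53, and the fibrinogen genes FGA and FGG by -1.19 ± 0.28 and -1.53 ± 0.34. PSPH differed by -1.61 ± 0.28, EGR1 by -1.41 ± 0.29 and the p53 target ZMAT3 by -1.44 ± 0.33.

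The autophagy genes SQSTM1, MAP1LC3B and TFEB, and HMOX1, had differences of -1.58 ± 0.49, 1.87 ± 0.52, -2.40 ± 0.67 and -1.49 ± 0.44 (adjusted p = 0.069, 0.0537, 0.0541 and 0.060). All 4 passed without ATP7B KO untreated replicate 3 (adjusted p = 4e-05, 0.00023, 0.0042 and 6.4e-05) and with DESeq2 (0.019, 0.012, 0.013 and 0.010). Without the libraries that stood apart the MAP1LC3B difference was 0.86 and the HMOX1 difference -0.44 (adjusted p = 0.0041 and 0.043). MT1X was at -0.84 ± 0.43 and MT2A at 2.10 ± 1.09 (adjusted p = 0.18 and 0.19). Autophagy genes called for the difference were 0 of 42 with edgeR, 17 at an unadjusted p under 0.05, 13 with DESeq2 and 22 with limma voom (9 more positive and 4 more negative adjusted over the list alone, camera adjusted p = 0.42). Without the libraries that stood apart the list median of the difference went from 0.12 to 0.19.

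Camera called 9 lists for the difference of the copper effects, and 0 with an estimated correlation. The list of ribosomal protein genes passed (0 adjusted over the list alone, camera adjusted p = 7.1e-08, adjusted p = 0.47 with an estimated correlation), and its single genes called were 0 of 52 with edgeR, 33 at an unadjusted p under 0.05, 12 with DESeq2 and 48 with limma voom. The list of nuclear-encoded respiratory chain genes also passed (0 adjusted over the list alone, adjusted p = 0.00035, 0.47 with an estimated correlation), with 0 of 34 with edgeR, 15 at an unadjusted p under 0.05, 6 with DESeq2 and 25 with limma voom. Both lists had a more positive median in KO cells and were low in the libraries that stood apart, with median shared deviations of -0.98 and -0.77. Immediate early, G2/M, endoplasmic reticulum chaperone and lysosome genes, also called with a more positive effect, were low there too (-0.69, -0.55, -0.51 and -0.49). Leaving out 1 library moved the count of 545 calls to 13, 14 and 23 without wild type untreated replicates 1, 2 and 3 and to 40 and 36 without wild type copper replicates 1 and 2. It moved to 29, 71 and 5882 without ATP7B KO untreated replicates 1, 2 and 3 and to 13, 19 and 17 without ATP7B KO copper replicates 1, 2 and 3. Of 25 genes named for this comparison or followed in its lists, 24 lost their call in at least 1 of these fits, and EDN1 kept it in all. Without the libraries that stood apart 1050 genes were called, of which 414 were among the 545. With library totals as the only scaling 960 genes were called, and 13.1% in place of 25.5% of them had a more positive copper effect in KO cells. That share was 44.7% with no filter, 43.0% without the libraries that stood apart, 52.7% with limma voom and 49.9% without ATP7B KO untreated replicate 3. It ran from 31.0% to 64.3% with 1 library left out, so which direction held the majority depended on the fit.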

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

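The tests of a wrong label, of the libraries that stood apart and of a difference between the lines other than the edit were chosen only after the result was seen, as were the counts of splits and the fits without those libraries and with limma voom.

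A difference between the lines in their copper effect, tested as an interaction, marked 545 genes. The largest positive differences were EDN1 at 7.26, CCN1 at 5.03, CD9 at 4.88, SNAI1 at 4.61 and CCNG2 at 4.39 on the log2 scale. The largest negative ones were IL21R at -6.00, ARSI at -5.09, NRTN at -4.69, ONECUT1 at -4.07 and CES1 at -4.04. Total counts without and with copper were 174 and 20 in wild type and 2 and 82 in KO cells for EDN1, 493 and 317 in wild type and 35 and 1167 in KO cells for CCN1 and 64 and 6 in wild type and 20 and 113 in KO cells for CD9. For SNAI1 they were 24 and 64 in wild type and 3 and 444 in KO cells, and for CCNG2 106 and 34 in wild type and 4 and 54 in KO cells. They were 36 and 88 in wild type and 26 and 2 in KO cells for IL21R, 17 and 24 in wild type and 407 and 46 in KO cells for ARSI and 71 and 41 in wild type and 57 and 3 in KO cells for NRTN. For ONECUT1 they were 162 and 44 in wild type and 236 and 11 in KO cells, and for CES1 35 and 102 in wild type and 94 and 46 in KO cells. These totals are raw and the groups differ in depth, so a lower total need not be a lower level. In wild type cells NRTN was at 6.33 ± 0.72 CPM untreated and 6.30 ± 2.4 CPM with copper. CCN1 was there at 43.8 ± 12.1 CPM untreated and 42.3 ± 50.4 CPM with copper. The fitted differences of genes with 2 to 4 counts in a group rest on those few counts and carry their counting error.

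The same test marked 9 lists by camera, each with a preset correlation and none with an estimated one. A more positive copper effect in KO cells was found for ribosomal proteins (adjusted p = 7.1e-08), nuclear-encoded respiratory chain genes (0.00035), lysosome genes (0.0039) and G2/M genes (0.0051). It was also found for endoplasmic reticulum chaperones (0.014), glycolysis and hypoxia genes (0.014), immediate early genes (0.039) and the proteasome (0.039). Mitochondrially encoded genes had a more negative copper effect (0.039). Without the 3 libraries that stood apart, named below, which leaves ATP7B KO untreated replicate 3 alone in its group, the median difference went from 1.37 to 0.37 for ribosomal proteins and from 1.18 to 0.30 for respiratory chain genes. It went from 0.89 to 0.33 for lysosome genes, from 0.89 to 0.21 for G2/M genes and from 0.87 to 0.42 for endoplasmic reticulum chaperones. It went from 1.34 to 0.46 for immediate early genes, or from 1.18 to 0.38 without the members that had 0 counts in a group. These 6 lists were low in those libraries. It went from 0.42 to 0.30 for the proteasome, and moved away from 0, from -0.62 to -1.01, for mitochondrially encoded genes. For glycolysis and hypoxia genes it went from 0.50 to 0.66, or from 0.49 to 0.53 without the members that had 0 counts in a group. With the replicate number as a block, immediate early and mitochondrially encoded genes missed the threshold (adjusted p = 0.0551 for each). With an estimated correlation the adjusted p of these 9 lists ranged from 0.30 to 0.49.

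Wild type copper replicate 1 and ATP7B KO untreated replicates 1 and 2 stood apart from their groups. Lower depth stays open as a part of the cause. Thinning ATP7B KO untreated replicate 3 to the depth of replicate 2 moved it in a direction correlated at -0.0180 with the deviation. Thinning draws a new random loss, which other libraries do not share, so a value near 0 was likely whatever the cause. A difference in copper exposure was not decided. The shared deviation was correlated across genes at 0.126 with the wild type copper effect and at 0.0280 with the KO one. Both sides use ATP7B KO untreated replicate 3 and wild type copper replicates 2 and 3, which biases these values. Of lists that rose with copper, metallothioneins had a median shared deviation of -1.41, heat shock genes -0.11 and NF-kappaB genes 0.62. A wrong genotype or treatment label was not seen in these 3 libraries. At the lowest 76.7% of 60 genotype markers (95% interval 64.0% to 86.6%) lay on the labelled side, in ATP7B KO untreated replicate 2. The interval counts genes of 1 library as independent. The label of ATP7B KO untreated replicate 3, which helped to choose the markers, was not tested. RNA quality and library batch were not testable from the labels, and weights fitted in limma voom were lowest for ATP7B KO untreated replicate 3 (0.0657), so the group does not show which of its libraries is atypical.

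The 545 interaction calls may come in part from the libraries that stood apart. Of these calls 76.0% (414 genes) were also made in the same direction both without those 3 libraries and without ATP7B KO untreated replicate 3. The fit without ATP7B KO untreated replicate 3 called 5882 genes and kept all 545, so it could hardly have lost any. The share was therefore set by the fit without the 3 libraries, in which that replicate was alone in its group. It was assumed there to vary like the other groups. Of 60 drawn splits of the 12 libraries, 3 gave at least as many calls as the real one, which is included, and the highest other gave 3554. Both splits above the real count exchanged the treatment labels of all KO libraries and so hold the copper effect itself, which points to a structure of the samples. These splits therefore neither exclude chance nor speak for it. A biological difference between the lines stays open beside the effect of these libraries.

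Glycolysis and hypoxia genes were lower in KO cells in both treatments. In copper the list median went from -1.34 to -1.20 without the libraries that stood apart, with 2 wild type and 3 KO libraries left. Since 21 of 29 members were then called lower, the libraries that stood apart were excluded as the whole cause there. Untreated they stay open as a part of the cause, since the 27 members called lower rest on ATP7B KO untreated replicate 3 alone, assumed to vary like the other groups. A difference between the lines other than the edit cannot be told apart from an effect of the edit, because the labels give 1 KO line and the list median of -1.83 fits either. Oxygen and culture density were not testable from the labels.

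For the other 4 comparisons, 6 libraries make 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, gave as many calls, with 1648 and 3721 for copper in wild type and KO cells and 3521 and 1525 for KO against wild type untreated and in copper. The highest other split gave 0 in each.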

How the results depend on the processing

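The fit without the 3 libraries that stood apart and the limma voom fit were chosen only after the results were seen, as were the counts without a library outside the comparison. Without the 3 libraries ATP7B KO untreated replicate 3 was alone in its group, and was assumed to vary like the other groups.

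Of 280 results of 171 genes other than ATP7B, 263 were called, and none reversed in any setting run. With relative log expression factors, DESeq2 and library totals every call in the first 4 comparisons kept its threshold, except MT2A in untreated KO against wild type cells with totals. Leaving out 1 compared library kept, ATP7B again aside, 63 of 68 gene calls for copper in wild type, 71 of 73 for copper in KO, 53 of 55 and 37 of 42 for KO against wild type untreated and in copper, and 1 of 25 for the interaction. The corresponding list calls kept were 16 of 18, 12 of 16, 6 of 9, 6 of 10 and 5 of 9.

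Counts of calls moved more. Copper in wild type called 4784 genes without the 3 libraries, 3044 with only the 6 compared libraries, 5443 with limma voom and 734 to 1382 with 1 compared library left out, and 3779 without ATP7B KO untreated replicate 3. Copper in KO called 1853 with the 6 libraries, 5843 with voom and 2372 to 6635 with 1 left out. KO against wild type called 1421, 5971 and 2058 to 6738 untreated in the same settings. In copper it called 4527 without the 3 libraries, 2694 with the 6, 5028 with voom and 675 to 1242 with 1 compared library left out, and 3561 without ATP7B KO untreated replicate 3. The interaction called 960 with library totals, 2366 with no filter, 113 with the replicate number as a block, 1050 without the 3 libraries, 1768 with DESeq2, 5461 with voom and 13 to 5882 with 1 left out. The shared copper calls numbered 2880 without the 3 libraries, 1938 with voom and 484 to 1342 with 1 left out. Samples share only a number, and of 18 same-numbered pairs 2 correlated over 0.1, so the block takes degrees of freedom without a known pairing. These 2 were wild type copper and ATP7B KO untreated replicates 3 (0.610) and replicates 1 (0.495). Wild type copper replicate 1 and ATP7B KO untreated replicate 2, with unlike numbers, were at 0.407. A batch shared by these libraries was not testable from the labels. With all 12 libraries copper called more genes in KO than in wild type cells (3721 against 1648). With only the 6 compared libraries it called fewer (1853 against 3044). The order of these counts therefore depended on which libraries shared the estimate of the spread, and does not show a larger response in KO cells. The cause of the other moves was not tested.

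Camera lists called in untreated KO against wild type cells numbered 2 with an estimated correlation and 17 with no filter, in copper 4 with an estimated correlation, and for the interaction 0 with an estimated correlation and 18 without the 3 libraries. The ATF4 list reversed for the interaction without the 3 libraries (adjusted p = 0.039), and the cause was not tested. ATP7B was at -1.05 with copper in KO cells without the 3 libraries, and with 1 library left out at -1.69 to -1.44 with copper in wild type cells, -0.95 to -0.27 with copper in KO cells and -1.10 to -0.40 in untreated KO against wild type cells. Depth limits what was seen, since 3 counts equal 0.783 to 3.07 CPM.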

Other observations

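The list and its set test were planned, but the hypothesis below was set against that test only after the result was seen. The fit without the libraries that stood apart was also chosen after it.

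The title of the series names autophagy, and autophagy genes were higher with copper in both lines by camera. A larger autophagy response to copper in KO cells was a hypothesis. The set test of the difference of the copper effects gave an adjusted p of 0.422 for the 42 genes of the list, which leaves the hypothesis open, and a miss of the threshold does not show that the responses were alike. Without the libraries that stood apart the list median of the difference went from 0.12 to 0.19. That value rests on ATP7B KO untreated replicate 3 alone in its group, whose replicates agreed least. Transcript levels do not measure autophagic flux.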
